A study of Beta macrocarpa with 3 samples.

How the data were processed

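Small RNA from systemic leaves of Beta macrocarpa, a wild relative of sugar beet, was compared between plants inoculated with Beet necrotic yellow vein virus (BNYVV) and plants given water, at 15 days post inoculation and the 5-leaf stage. Per the labels' protocols, plants were kept at 24 °C with 16 h of light, and RNA under 300 nt was tailed, tagged and stained with Cy3 or Cy5. Each of the 3 arrays carried 1 infected and 1 water sample. Infected RNA was stained with Cy5 on arrays 1 and 3 and with Cy3 on array 2, so the dyes were exchanged once but not balanced, and 33.3% of any probe-specific dye effect stays in a mean over the arrays. The labels number the pairs but do not say whether they came from separate plants or pools, so part of the spread between these arrays may be technical. The p-values of the linear models measure that spread.

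The scans were made on an Axon GenePix 4000B at 10 µm pixels, per the file headers, with gains set per channel (400 to 430 for Cy3 and 480 to 510 for Cy5). The image software was not given in the sources used here. The deposited spot intensity of each channel is the median pixel density before background subtraction. Every array had 5022 spots, of which 4815 were 1605 probes in 3 repeats and 207 were controls (31 empty spots, and repeats of 19 spike and 6 5S rRNA probes). The deposited summary sheets hold each probe's mean intensity per channel after background subtraction and LOWESS, per the file headers. They also hold a detection p-value per channel and a p-value of the difference between channels from the authors, whose tests are not named in the headers. The deposited log2 ratio of the summary sheets is infected over water on every array, which was checked against the channel means. The value table of the series holds the same log2 ratios at 2 decimals from the authors in another row order without probe names: all 1605 rows matched a summary triple, so its direction and scale are those of the summary sheets, and its columns had medians of -0.01, -0.01 and 0.02. The headings of the spot sheets of arrays 1 and 3 carried each other's pair number, but the spots of all 3 sheets correlated best with the summary of their own array, and the groups and dyes are the same under either number. The brightest spot reached 54309, under the scanner's ceiling of 65535.

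Spot intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected with normexp at an offset of 50 over all spots, since no local background was used. Loess was fitted within each array with control spots at weight 0, and the 3 repeats of a probe were averaged. Each array's log2 ratio was turned so that a positive value means more signal in infected leaves. Probes entered the tests when the authors' detection p-value was under 0.01 in at least 2 of 3 infected or 2 of 3 water channels, which kept 522 probes. A linear model with an intercept was fitted with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Loess centres each array, so a ratio states a change relative to the bulk of the probes on that array. Levels per group are log2 signals per channel after Aquantile between arrays and are open to dye bias. Where a probe was not detected in a group on any array, the fold is given as a lower bound. It sets the brighter group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal of a detected probe.

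Probe names give a miRNA number for 213 probes, called catalogued here, while 1392 names carry none (1332 beginning PC and 60 beginning miRn) and are called candidates. Families were formed from the number and the arm in the probe name, averaging the tested probes of a family per array, since probes that differ by few bases can bind the same RNA. The lists of families, the rule for named probes and the alternatives, except those said to be added later, were chosen before the data were examined. Conserved families were put by textbook target into 9 lists: silencing machinery, immune receptors, auxin, phase change and leaf development, copper, nutrients, MYB and phenylpropanoids, and, as other tissues, meristem or bud and phloem sap. The MYB and phenylpropanoid list had 0 probes on the arrays. Lists were tested with limma's fry, which asks whether members move one way on balance, and with camera, which sets them against the other probes, at a preset correlation of 0.01 and with an estimated one. At the preset correlation, camera's p-value judges a list against the spread over probes, not that between arrays. The named probes are the 12 higher and 12 lower with the largest mean log2 ratio among those past the threshold with one sign on all arrays, at most 2 per miRNA number; the brightest tested probe of up to 4 families per list; and the 5 brightest probes. Where fewer than 5 passed in a direction, the 10 largest with a log2 ratio of at least 1 would have been given; this was not needed. After seeing the data, probes were sorted by sequence into guide and passenger strands. A guide overlaps a reference strand of 1 of 22 families by at least 15 bases with at most 4 mismatches, and a passenger pairs with it over at least 15 bases with at most 5 mismatches. Sequence clusters allow at most 2 mismatches over the same overlap.

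The fit was tested on simulated data before use, starting from background-corrected signals with the arrays' own dye curves and 120 changed probes among 522 in each of 10 simulations. The correction of background itself was not simulated. Changes of 1 and 2 on the log2 scale were recovered in 100% of cases in both directions, and those of 0.6 in 93% of raised and 90.5% of lowered probes. On average 4.52% of the calls fell on unchanged probes. A list of 15 probes raised by 0.6 passed fry in 5 and camera with the preset correlation in 10 of the 10 simulations; camera with an estimated correlation was not simulated. Unmoved lists came under 0.05 in 7.5% of cases by fry and 2.5% by camera with the preset correlation. The simulated probes varied independently with a common SD, and the lists held random probes. Real lists hold probes of near-identical sequence, with estimated correlations from -0.02 (meristem or bud) to 0.88 (phloem sap). The shares recovered and the error rates may therefore not carry over to the real data.

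The alternatives were a dye term, other background corrections and offsets, other normalizations, the authors' values, other filters, the median over repeats, each array left out, the channels without the array as a pair, other variance models and other ways of forming families and lists. Scaling to spike or 5S rRNA controls was added after seeing the data. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. No genome was used here, so no coordinates are given, and targets of miRNAs are stated as general background.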

Results

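MicroRNAs were measured in systemic leaves of Beta macrocarpa, a wild beet, 15 days after inoculation with BNYVV, a soil-borne virus of beets, or with water. The 3 arrays each compared 1 infected with 1 water sample directly. Of the 1605 probes, 32.8%, 27.4% and 26.4% were detected in the infected channels and 24.9%, 32.8% and 35.5% in the water channels of arrays 1, 2 and 3. Background levels lay between 88.2 and 173 intensity units, with an SD between 14.6 and 36.5. The number of arrays limits the precision of every value. Of 213 catalogued probes 192 (90.1%) were tested, and of 1392 candidates 330 (23.7%).

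The first question was which miRNAs differ between infected and healthy leaves. The largest rises were mostly in probes for arms opposite the usual functional strand of conserved miRNAs. The miR166 5p probe aly-miR166g-5p_R+1_1ss20GA (GGAAUGUUGUUUGGCUCGAAGU) was 14.3-fold higher in infected leaves (log2 ratio 3.84 ± 0.13, SD, n = 3). The probe miR160a-3p_1ss16TA rose 9.54-fold (3.25 ± 0.22), miR396b-3p 8.52-fold (3.09 ± 0.19), miR162a-5p_L-1 8.25-fold (3.04 ± 0.35) and miR168c-3p 8.01-fold (3.00 ± 0.26). In all, 84 of 522 tested probes were higher and 27 lower by limma, and the 111 had the same sign on all 3 arrays. A log2 change of at least 1 was reached by 58 of the higher probes (57 with probes not detected in water at their lower bound) and 0 of the lower. Probes with near-identical sequences are counted apart here: the higher probes fell into 43 sequence clusters and the lower into 8.

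The probe aqc-MIR166d-p3_1ss21GT rose 13.1-fold (3.71 ± 0.35). Its sequence, GGAAUGUUGUUUGGCUCGAAUC, is close to that of the miR166 5p probe above although its name gives the other arm. The miR159 probe vvi-MIR159c-p5_1ss1CT was not above background in water on any array and was at least 8.63-fold higher in infected leaves. Its adjusted p of 2.7e-07 (limma) belongs to the fitted log2 ratio of 3.19, not to this bound. The log2 levels were 10.86 ± 0.045 in infected leaves and 7.67 ± 0.0078 in water (SD, n = 3). The water level is that of an undetected signal, so its small SD does not measure agreement of replicates. The miR390 3p probes aly-miR390a-3p_R+1_2ss8CT21AT and miR390a-3p_R+1_1ss8CT rose 5.70-fold (2.51 ± 0.47) and 5.68-fold (2.51 ± 0.42). Among candidates, PC-5p-15248_87 (UAAUUUGAAGGGUUGUGGUUA) rose 5.95-fold (2.57 ± 0.36), PC-5p-276799_8, a shorter probe within the same sequence, 5.84-fold (2.55 ± 0.38) and PC-5p-11205_106 (AGGAUUAGGAUCGGGUUGGUC) 5.50-fold (2.46 ± 0.30).

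Declines were smaller and lay mostly in probes for the usual functional strands of miR396, miR164, miR398, miR172 and miR169. The miR396 probes miR396a-5p and miR396b_R+3, of a family that targets growth-regulating factors, fell by 0.89 ± 0.40 and 0.83 ± 0.29 on the log2 scale (SD, n = 3), or 1.85-fold and 1.78-fold. The miR164 probes, of a family that targets NAC transcription factors, fell by 0.85 ± 0.31 (ath-miR164a_R+1_1ss21AT) and 0.71 ± 0.23 (miR164a). The miR398 probes miR398b_1ss21GT and miR398b, whose family targets copper/zinc superoxide dismutases, fell by 0.81 ± 0.10 and 0.75 ± 0.14. The miR172 probes miR172b_L+2R-2 and miR172b_1ss1AC fell by 0.77 ± 0.29 and 0.74 ± 0.17, and PC-3p-222569_10, a candidate of nearly the same sequence (CGAAUCUUGAUGAUGCUGCAUUU), fell by 0.75 ± 0.31. The miR169 probes sly-miR169a_R+4 and miR169e-5p fell by 0.73 ± 0.36 and 0.66 ± 0.21, and the candidate PC-5p-65970_27 by 0.56 ± 0.33. The adjusted p of these 12 probes lay between 0.0041 and 0.049 (limma). Of 18 alternatives fitted to all probes, 10 lost the call of PC-5p-65970_27 and 3 or 4 that of each of the other 11.

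**Figure D1:**
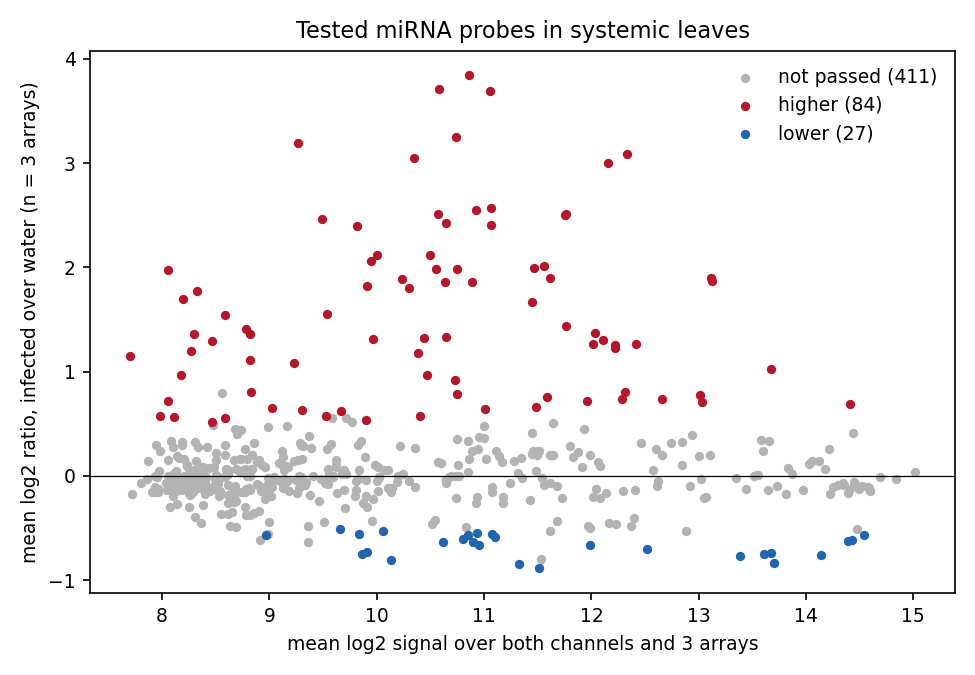
Mean log2 ratio of infected over water (vertical axis, mean of 3 arrays) against mean log2 signal over both channels (horizontal axis) for the 522 tested probes, with 84 higher probes in red, 27 lower probes in blue and those that did not pass in grey. The higher probes reach 3.84, while the lower ones stay above -1.

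The calls depended on array 2, on array 3 and on the scaling. By limma without array 2, 48 probes were higher and 0 lower (27 lower at an unadjusted p under 0.05). With a dye term in the model it was also 48 and 0 (36 lower unadjusted), and without array 3 it was 64 and 11. The 27 probes with the lowest mean on arrays 1 and 3, chosen after seeing the data, had a median of -0.19 on array 2. That array carried the dyes the other way. The 95% bootstrap interval of the median was -0.62 to 0.57, and 15 probes were below 0. Only 13 of these 27 were among the probes called lower. Setting each array to its spike controls, also chosen after seeing the data, moved the median of the tested probes to 0.20. It left 36 higher and 0 lower (0 lower unadjusted). The sources used here do not say whether both samples received equal amounts of spikes. The spike medians differed between arrays (-1.23, -0.09 and 0.71), and this scaling adds that spread to the ratios of every probe. Setting it to its 5S rRNA controls moved the median to -0.18 and gave 61 higher and 33 lower. No called probe or family changed sign under either scaling, but each scaling moved every mean by the same amount. That amount was smaller than the called values, such as 0.35 for the family miR159-3p. The kept signs therefore say nothing more.

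Averaged by family and arm, 34 of 90 family units rose and 9 fell. The highest were miR160-3p (3.25 ± 0.22, SD, n = 3), miR162-5p (3.04 ± 0.35), miR168-3p (3.00 ± 0.26), miR166-5p (2.78 ± 0.21, 6 probes), miR390-3p (2.51 ± 0.44), miR159-5p (3 probes, at least 2.37 with the probe not detected in water at its bound), miR396-3p (2.11 ± 0.28, 5 probes), miR171-5p (1.94 ± 0.27), miR168-5p (1.89 ± 0.13), the probes named miR168 without an arm (1.88 ± 0.23) and miR535-3p (1.86 ± 0.29). Among the rest miR390-5p rose by 1.67 ± 0.39, miR157, which targets SPL transcription factors, by 1.24 ± 0.36 and miR393, which targets auxin receptors, by 1.23 ± 0.32. The units of the related miR156 were less even. The unit miR156 rose by 0.69 ± 0.24, with probes from -0.21 to 1.31, and miR156-3p by 0.46 ± 0.31, with probes from -0.43 to 1.37. The unit miR156-5p (-0.18 ± 0.16) did not pass. The families that fell were miR398 (-0.78 ± 0.12), miR172 (-0.75 ± 0.23), miR164 (-0.74 ± 0.28), miR396 (-0.70 ± 0.30), miR169-5p (-0.66 ± 0.21), miR169 (-0.61 ± 0.10, 8 probes), miR171-3p (-0.51 ± 0.34), miR5139 (-0.49 ± 0.31) and miR171 (-0.44 ± 0.37).

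Other family units stayed close to 0 and did not pass: miR159 (-0.11 ± 0.10, 16 probes), miR166 (0.09 ± 0.17, 5 probes), miR167 (-0.02 ± 0.18), miR319-3p (-0.13 ± 0.02) and miR408-3p (-0.09 ± 0.32). The means of some units hide unlike probes. That of miR166-3p (1.35 ± 0.17) covers probes from 0.12 to 3.71 and that of miR396-5p from -0.89 to 1.89. That of miR159-3p covers -0.15 to a fitted 1.30. The latter is a probe not detected in water, whose bound is lower than this (unit mean at its bound 0.34). Under the filter that required detection in both channels of all arrays, miR159-3p was at -0.12 and did not pass. The moderated variance of this fit was one common value for all families, and with each family's own variance, an alternative chosen after seeing the data, 16 rose and 3 fell. Relative to spike controls 14 rose and 0 fell (0 lower unadjusted by limma), relative to 5S rRNA controls 22 rose and 9 fell, and without array 2, 28 rose and 4 fell.

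**Figure D2:**
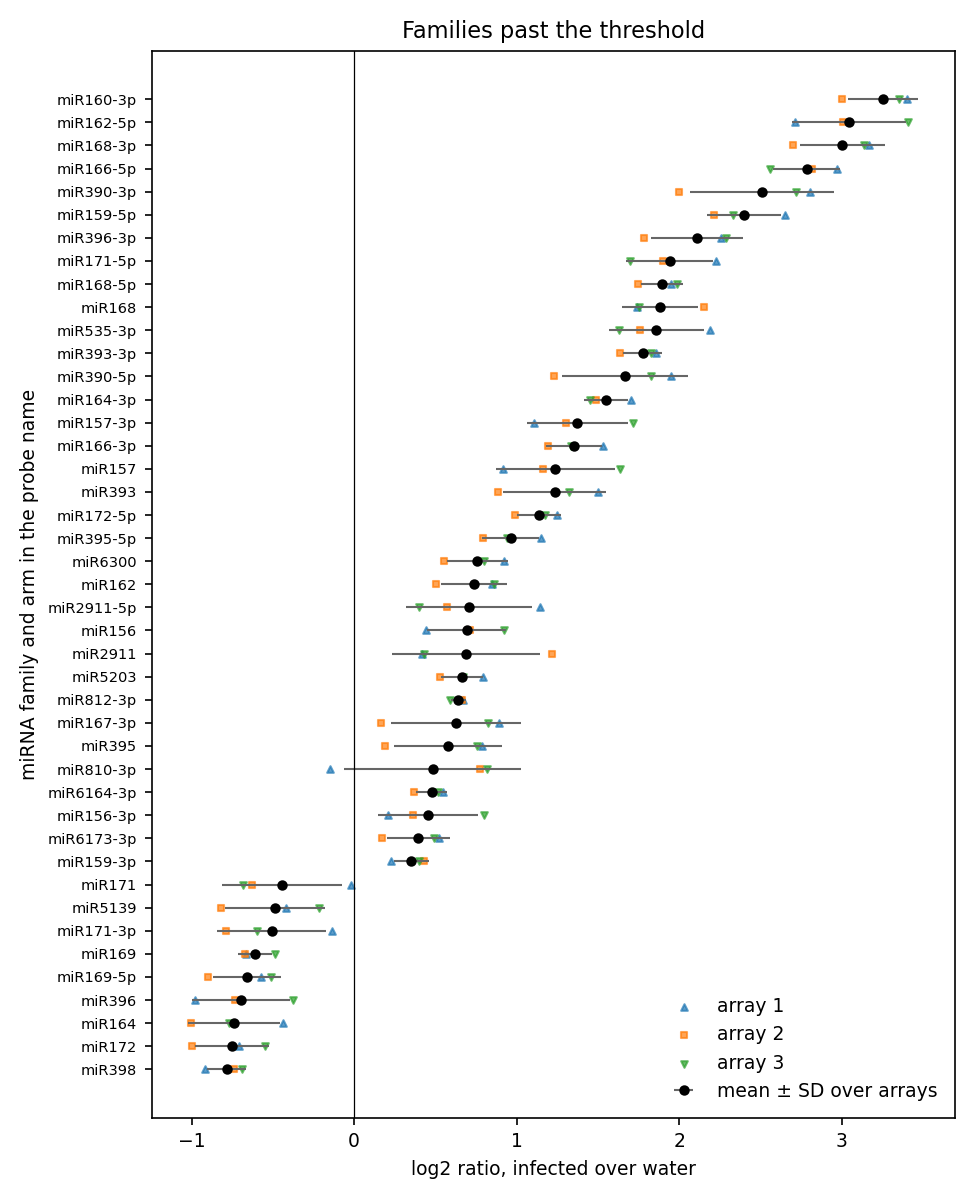
Log2 ratio of infected over water for the 43 family units past the threshold, with black points and bars for the mean ± SD over 3 arrays and coloured markers for each array; fitted values are drawn also for miR159-5p, miR159-3p, miR393-3p and miR395-5p, which hold a probe not detected in water. The 34 higher units reach 3.25 and the 9 lower units -0.78.

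The lists fixed beforehand group these miRNAs by the known target, or the tissue, of their family. Members were matched on the family number alone, so passenger probes count too. The targets are those of the usual functional strand, so a rise of passenger probes does not by itself bear on them. In the silencing list, which holds the regulators of DCL1 (miR162), AGO1 (miR168) and AGO2 (miR403), 6 of 8 probes rose, 0 fell and 2 did not pass. Adjusted over the list alone, 6 were higher and 0 lower. Sorted by strand after seeing the data, 4 of 6 guide and 2 of 2 passenger probes rose. The probe miR168b rose 3.65-fold (1.87 ± 0.23, SD, n = 3) and miR162 1.67-fold (0.74 ± 0.20), whereas miR403a_1ss20TC had a log2 ratio of -0.17 ± 0.36. The call of miR168b held under the 18 alternatives fitted to all probes. By limma miR162 did not pass with the dye term (log2 ratio 0.68, adjusted p = 0.083) or with the authors' values (adjusted p = 0.059). It also did not pass without array 2 (0.078), without array 3 (0.133) or relative to spike (0.998) or 5S rRNA controls (0.137). The list moved up by fry (adjusted p = 0.0089), and against other probes by camera with the preset correlation (adjusted p = 0.00048), with adjusted p = 0.287 with an estimated correlation. That estimate was 0.007, below the preset 0.01, so a higher correlation is not what raised this p.

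In the auxin list 8 of 15 probes rose, 0 fell and 7 did not pass, and the same numbers came out when adjusted over the list alone. By strand, 3 of 10 guide and 5 of 5 passenger probes rose. The probe miR393a_R+1 rose 2.16-fold (1.11 ± 0.11) but did not pass relative to spike controls, beside the miR390 3p probe above, whereas miR160a-5p, which targets auxin response factors, had a log2 ratio of 0.14 ± 0.38 and miR167b-5p of -0.03 ± 0.14. The list passed fry (adjusted p = 0.047), but not with plain background subtraction (0.0501), the median over repeats (0.055), detection required in both channels of all arrays (0.063) or without array 1 (0.181). Camera gave it adjusted p = 0.00081 with the preset correlation and 0.459 with an estimated one.

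The phase change and leaf development list had 32 of 81 probes higher, 11 lower and 38 that did not pass; adjusted over the list alone, 32 were higher and 14 lower. The rises were mostly in passenger strands, of which 26 of 28 rose and 0 fell, while of 49 guide probes 5 rose and 11 fell. The list passed fry upward (adjusted p = 0.014, and 0.145 without array 1). Camera gave it adjusted p = 0.017 with the preset correlation and 0.459 with an estimated one. Its mean log2 ratio was 0.62 and its median 0.02. The brightest probes of 4 of its families did not rise: ath-miR159a_R-3 had a log2 ratio of -0.14 ± 0.15 and ath-miR166a_L+1R-1 of 0.07 ± 0.23, ath-miR396b_1ss2TC fell by 0.57 ± 0.29, a call lost under 11 of 18 alternatives, and miR172b_1ss1AC fell as given above. The meristem and bud list shares miR164 and miR166 with it: 8 of 18 probes rose and 3 fell, also when adjusted over the list alone. The 8 that rose were the list's 8 passenger probes, and of its 10 guide probes 0 rose and 3 fell. It had adjusted p = 0.0089 by fry, upward. By camera it had adjusted p = 0.0030 with the preset correlation and 0.287 with an estimated one. Its estimated correlation was -0.02, so a higher correlation is not what raised the p here either.

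The remaining lists did not pass fry. By camera with the preset correlation the nutrient list moved down (adjusted p = 0.017) and the phloem sap list up (0.029). Both had 0.459 with an estimated correlation. When probes were averaged by family and arm, preset camera passed only the silencing list (adjusted p = 0.0095). It then gave 0.446 for nutrients, which turned upward by fry, 0.524 for phloem sap and 0.095 for auxin. Phase change and leaf development had 0.524 and meristem or bud 0.434. Fry still passed silencing (0.013), auxin (0.034), phase change and leaf development (0.014) and meristem or bud (0.014) upward. The copper (0.057) and immune receptor (0.522) lists did not pass preset camera. Fry's mixed test, in which members may move either way, had unadjusted p of 0.0032 for nutrients, 0.0079 for copper, 0.035 for phloem sap and 0.36 for immune receptors. In the copper list 2 of 5 probes fell, both miR398b, also when adjusted over the list alone, while miR398c-5p_2ss13AG15TC (0.24 ± 0.29) and gma-MIR408b-p3_1ss7GT (-0.10 ± 0.28) did not pass (fry adjusted p = 0.155). In the nutrient list 2 of 17 probes rose and 9 fell (adjusted over the list alone, 4 and 9; fry adjusted p = 0.155). Its falling probes were of miR169, which targets NF-YA factors, such as bna-miR169g_1ss22CA (-0.58 ± 0.26), whose call was lost under 10 of 18 alternatives. The rising ones were of miR395, a regulator of sulfate assimilation, of which miR395a_2ss1AC21CT had a log2 ratio of 0.56 ± 0.37 that did not pass but did under 4 alternatives. These same miR395 probes were the 4 tested in the phloem sap list, with 2 higher, or 4 when adjusted over the list alone (fry adjusted p = 0.083). That list passed fry with the authors' values (adjusted p = 0.047) and with the channels taken apart (0.0062). The immune receptor list had 1 probe, osa-MIR2118e-p3_1ss13TA, at -0.14 ± 0.20, which did not pass (fry adjusted p = 0.36, and 0.047, downward, without array 1; 0 calls adjusted over the list alone). Its family had no reference strand, so the probe was not sorted by strand. Whether it measures the strand that acts on immune receptors is not known. With the dye term, without array 2, without array 3, and relative to either set of controls, 0 lists passed limma's fry. At an unadjusted p under 0.05 these settings gave 4, 4 and 3 lists, 0 relative to spike controls and 2 relative to 5S rRNA controls.

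Candidates were compared with catalogued miRNAs as a set. Of 330 tested candidates 24 rose and 5 fell (8.79% changed), against 60 and 22 of 192 catalogued probes (42.7%). Their mean log2 ratio was 0.07 against 0.44, a difference of -0.37, while the medians were closer (-0.01 against 0.07). Camera gave p = 0.0045 at the preset correlation and p = 0.342 with an estimated correlation. The candidates as a set did not pass fry. Under the filter that required detection in both channels of all arrays the difference was -0.29 and no longer past the threshold of camera. The brightest probe on the arrays was a candidate, PC-3p-4827_201, with a log2 ratio of 0.04 ± 0.52 (SD, n = 3). It was followed by miR167b-5p, ath-miR167a_R+1_1ss21AG (-0.01 ± 0.07), ath-miR159a_R-3 and ath-miR159a_R-2_1ss19CT (-0.12 ± 0.25), none of which passed.

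Log2 ratios correlated across the 522 probes, which are not independent replicates, with Pearson's r of 0.73 between arrays 1 and 2, 0.793 between arrays 1 and 3 and 0.858 between arrays 2 and 3 (Spearman's rho 0.456, 0.495 and 0.578). The sign was the same on all arrays for 42.3% of probes, where chance gives 25%. No probe had a dye effect past the threshold in the limma fit with a dye term (0 of 522; 10 at an unadjusted p under 0.05), a fit with 1 residual degree of freedom per probe.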

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

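Control spots lie outside the comparisons and carried a signal that was not equal in the channels. The 5S rRNA probes had a median log2 ratio of infected over water of 0.17 on array 1 and 0.42 on array 2, above 0 by more than their SD over 6 probes (0.149 and 0.065), and -0.06 on array 3. The 19 spike probes had a median of 0.71 on array 3 (SD over probes 0.261), -0.09 on array 2 and -1.23 on array 1. These are values after loess, in which control spots had weight 0 but moved with the fitted curve. Before loess the tested probes had medians of 1.40, -0.13 and -0.23 on arrays 1, 2 and 3, against 0.17, 0.01 and -0.02 after it. No explanation was tested for these values.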

How the results depend on the processing

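Scaling to controls, each family's own variance and robust variances for families were chosen after seeing the data. No called probe changed sign under the settings fitted to all probes, and of the called families 1 did, miR159-3p (-0.12 under the strict filter, detection in both channels of all arrays). Without background correction, with another offset, median centring, loess on detected probes, no filter, the strict filter, the median over repeats, robust variances and the channels taken apart, 99 to 129 probes, 36 to 43 families and, where run, 3 to 5 lists were called. With a dye term 48 probes were called (48 higher, 0 lower) and 0 lists. Plain background subtraction gave 12 lower probes and the authors' values, or the series table of the same ratios, 16. The authors' p under 0.01 on all arrays gave 56 probes (46 higher, 10 lower). Relative to spike controls 36 probes (36 higher, 0 lower), 14 families (14 higher, 0 lower) and 0 lists were called, and relative to 5S rRNA controls 22 higher families and 0 lists. Families of 3 or more probes gave 15 calls (11 higher, 4 lower), with fewer families tested, and each family's own variance 19 (16 higher, 3 lower). The candidate difference was -0.29, no longer past the threshold, under the strict filter. The lowest correlation between arrays was 0.609 without a filter and 0.815 under the strict one. Apart from the smaller number of families and the spread between arrays that spike scaling adds, the cause of these moves was not tested here. The dye term is taken up under the other observations. Leaving out 1 array at a time gave 48 to 102 changed probes, 48 to 77 higher and 0 to 25 lower, 32 to 44 changed families (4 to 9 lower) and 0 to 3 lists. The lowest of each came without array 2, and that of lists also without array 3.

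The array is the pair in this design. With no replicate block, the channels taken apart, 106 probes (82 higher, 24 lower), 41 families and 5 lists were called; lists were not run with the intraspot correlation. The 41 named probes gave 734 values over 18 settings, of which 625 kept their direction and side of the threshold, 76 lost the call, 4 gained it and 29, not called in either, changed sign. Signal over background limits the dim probes: 11 changed probes were undetected in one group on all arrays.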

Other observations

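The sorting by strand, the tests of dye effects, the count with each family's own variance, the test of degrees of freedom alone and the count of splits for probes were chosen only after the results were seen. Sorting probes by sequence into those like the usual guide strand of 22 conserved families and those that pair with it as a passenger strand gave 81 guide and 43 passenger probes among those tested. Passenger probes rose in 36 cases, fell in 0 and did not pass in 7, while guide probes rose in 13, fell in 22 and did not pass in 46. By this sorting 18 families had both strands. The passenger log2 ratio exceeded the guide's in 16 of them (limma, adjusted p under the threshold) and was lower in 0. With probes not detected in water at their bound it was 14, without miR393 and miR395. That fit had one common variance for all families, and with each family's own variance the passenger was above the guide in 11, with miR167, miR168, miR169, miR393 and miR395 no longer among them. The gap was 3.11 in miR160, where the guide had 0.15 ± 0.35 (SD, n = 3), 2.80 in miR166 (guide 0.11 ± 0.09), 2.79 in miR396 (guide -0.71 ± 0.29), 2.42 in miR171 (guide -0.47 ± 0.35) and 2.29 in miR164 (guide -0.74 ± 0.28). It was 2.31 in miR162, 1.11 in miR168 and 0.84 in miR390, where the units of both strands rose, as they did in miR393 and miR395, with gaps of at least 0.22 and 0.31 (passengers not detected in water). In miR156 with miR157 the strands did not differ past the threshold (0.12, limma adjusted p = 0.468). Units of both strands rose there, but miR156-5p, at -0.18 ± 0.16, did not pass. In miR408 the gap was -0.01 (limma adjusted p = 0.947). Its passenger probe, gma-MIR408b-p3_1ss7GT, was sorted by sequence alone, and its name gives the same arm as the guide's. This family may therefore not compare both strands.

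Some candidates have the sequences of such strands. PC-3p-43363_38 (AUCAUGCAAUCCCUUUGGAUA), near the miR393 3p probe, was at least 2.44-fold higher in infected leaves, and PC-3p-29599_52 (GCUCUCUAUCUUCUGUCACCU), near the miR156 and miR157 3p strands, rose by 1.34 ± 0.35 on the log2 scale. These were chosen after their values were seen.

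The median gap between passenger and guide log2 ratios was 1.48 over the 18 families, also with undetected probes at their bound, and from 1.40 to 1.56 with 1 array left out. A probe-specific dye effect would leave a gap near 0 once a dye term is fitted. The gap was then 1.49, with a standard error of 0.299 over the 18 families. A bias of dim probes would raise others of the same signal. Tested probes whose names put them in none of the sorted families were matched to the passenger probes on mean signal. They had a median log2 ratio of 0.034, against 1.86 in the passenger probes. The difference was 1.83, with a bootstrap standard error of 0.149 over the 43 passenger probes. Probes of a family, such as the 7 of miR166, are not independent, so this may understate the error. Neither standard error measures the spread between arrays. Loess had already centred the bulk of the probes at each signal level. A matched median near 0 was therefore largely set in advance, so the matching cannot decide on a bias of dim probes. A shift in strand balance in infected leaves may remain as a hypothesis. Binding of viral or other RNA to these probes stays open too, since no viral sequence was used here, and sequencing of small RNA from both groups would tell these apart.

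The 27 lower probes lost their calls when a dye term was added. Their median log2 ratio was -0.64 (SD over probes 0.108) without and -0.66 (SD 0.133) with the term, but the called probes have one sign on all arrays, so this says little about a dye effect. Another choice, which leaves out array 2, took the 27 probes with the lowest mean on arrays 1 and 3. Their median on array 2 was -0.19 (95% bootstrap interval -0.62 to 0.57), with 15 below 0. Only 13 of them were among the probes called lower, so this cannot decide on those, and a dye effect in the lower probes stays open. Larger standard errors had been predicted and were not found: the median was 0.885 times that without the term. The total degrees of freedom fell from 9.93 to 3.36, and with the former number the dye-term values would call 25 of the 27 again. These probes were chosen for passing at that number, and their ratios and standard errors did not worsen, so most had to pass again. The count ties the lost calls to the degrees of freedom only as arithmetic and says nothing on a dye effect.

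Turning the sign of the arrays gives 4 splits, too few for a share under 0.05. Of the 4, 1 (the real one) gave 111 probes, 43 families and 4 lists, and the highest of the others gave 0 of each.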
